A study of Homo sapiens with 44 samples.

How the data were processed

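Poly-A RNA was sequenced from 12 libraries of the GAS41 experiment on a BGISEQ-500, and RNA from 6 libraries of the doxorubicin experiment on an Illumina HiSeq, per the labels. The submitters' processing notes list CASAVA 1.4, Trimmomatic 0.36, Bowtie 1.0.1, TopHat2 2.1.0, HTSeq and DESeq2 and the builds mm9 and hg19, without a role or an order for any of them, and the gene annotation is not stated. The 26 ChIP and input samples of the series were not analysed here, because the comparisons are of RNA levels.

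The deposited tables are named as counts, but their values are log2 values on a variance-stabilized scale, which the authors made from reads divided by a size factor per library. This was read from the values: each table has 1 lowest value shared by all its libraries, and the inverse of the transformation gives whole reads to within 0.01 for every value. The size factors found in this way equal median-ratio factors computed from the recovered reads. A value 1 log2 above the lowest stands for 39.4 normalized reads in the GAS41 table and 52.9 in the doxorubicin table, so log2 changes of genes with few reads are smaller than their folds. There are 18797 genes in the GAS41 table, and the table of the doxorubicin experiment has 21159. Of these names 18181 and 20410 are current or older gene symbols of the reference annotation, and neither table gives positions or identifiers other than names.

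A test on counts had been planned before the data were examined, and limma on the deposited values was used rather than edgeR because these are not counts. The count tests planned as alternatives, edgeR with RLE factors and DESeq2, were not run on the recovered reads either. Genes with at least 10 recovered reads in at least 3 libraries were tested, 14505 in the GAS41 table and 14195 in the doxorubicin table. Differences of the deposited log2 values were tested with limma (version 3.58.1, in R 4.3.3) with a mean-dependent prior variance and Benjamini-Hochberg adjustment over genes, called at an adjusted p of 0.05. All 12 GAS41 libraries entered 1 fit, and the 6 doxorubicin libraries another. Normalized reads are the recovered reads over the size factor, and their mean and SD over 3 libraries are given beside the change. Other tests were also run in R, and Python 3.11.15 with matplotlib 3.10.9 served for plots.

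Gene lists were fixed before the data were examined, and 23 of 26 had at least 3 tested genes. They were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over 161 tests (23 lists in 7 comparisons), and again with an estimated correlation and with fry. With an estimated correlation the interferon list remained called in each comparison of GAS41-KO or mut rescue. So did p53 targets and cholesterol genes in mut rescue over WT, p53 targets with doxorubicin, NF-kB genes and ribosome biogenesis genes in mut rescue over GAS41-KO, and G2/M genes in GAS41-KO and mut rescue over WT and between the rescue lines. The lists of blood and immune, endothelial and mitochondrially encoded genes had fewer than 3 tested genes and have no test; the closing section gives the blood and immune levels.

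Genes are named by a rule fixed before the data were examined. Genes given in the main comparisons whatever their values are YEATS4, CDKN1A, MDM2, MYC, SIN3A, HDAC1 and HDAC2. The 8 largest changes of each sign are given for doxorubicin and for GAS41-KO, and the 5 largest for the rescue comparisons among rescue lines and GAS41-KO. These genes had to be called, to have a mean of at least 5 CPM, and to have groups that do not overlap, and clone names, pseudogenes, microRNAs and snoRNAs were passed over. From each called list the 3 members with the smallest p may be named, and from the others up to 2.

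Return of the knockout changes was counted as genes called in GAS41-KO over WT and called in the opposite direction in a rescue line over GAS41-KO. Because both contrasts share the GAS41-KO libraries, the count was set beside 20 simulations of rescue libraries that do not differ from GAS41-KO. Overlap of GAS41-KO and doxorubicin changes was tested with Fisher's exact test over 13803 genes tested in both tables.

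The procedure was tested on simulated data with planted changes. Of genes planted at a fold of 1.5, the test found 80.6% for GAS41-KO over WT, 73.1% for mut rescue over GAS41-KO and 80.6% for doxorubicin, and at a fold of 2 it found 94%, 85.1% and 86.6%. All were found at a fold of 4. False calls made up 5.8%, 3.7% and 6.1% of calls. Simulated genes were drawn independently, with the same spread in every group, and no wt rescue comparison was simulated. In the GAS41 simulations 14288 of 14505 genes were unchanged, far more than the real calls leave. These rates therefore do not give the error of the real calls. A planted log2 change of 1 came out with a median of 0.75, 0.77 and 0.71 on the deposited scale.

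Alternatives tried were no filter on low reads, the replicate number as a block, a fit on the 2 groups alone and leaving out each library in turn. After the data were seen, voom on the recovered reads with the deposited size factors or TMM factors, quantile normalization of the log2 values and wt rescue replicate 1 alone in its group were added. The medians of the 23 lists were computed under each of these scalings, and those of called lists kept their sign, except that of oxidative phosphorylation genes in wt rescue over WT, which was 0 with quantile normalization.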

Results

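RNA was sequenced from 18 libraries of HCT116, a human colon cancer cell line. The question behind the series is how GAS41, the protein made by YEATS4, acts in transcriptional repression. GAS41 reads acylated histone H3 through its YEATS domain and is a subunit of the TIP60 and SRCAP chromatin complexes. In 1 experiment, 3 libraries came from cells given 500 nM doxorubicin, a topoisomerase poison that breaks DNA, and 3 from cells given the solvent DMSO. The other experiment had 12 libraries in 4 groups of 3. These groups were unedited cells (WT), GAS41 knockout cells (GAS41-KO), knockout cells that stably express tagged normal GAS41 (wt rescue) and knockout cells that stably express tagged GAS41 mutated in its YEATS domain (mut rescue). The 26 ChIP and input samples of the series were not analysed here.

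Depth lay between 16857982 and 18546135 reads per library in the GAS41 experiment and between 17442035 and 18894312 in the doxorubicin experiment. Genes are named by the symbols in the deposited tables, which give no positions. Levels below are normalized reads (reads over the size factor of the library) as mean ± SD with n = 3 libraries per group. Folds are ratios of these means, and log2 changes are on the deposited scale, which compresses genes of few reads. The largest rises and falls are ranked by these log2 changes, so a gene of few reads can have a larger fold and not be listed. Genes were called with limma at an adjusted p under 0.05. The labels describe 3 biological replicates per group in the GAS41 experiment and 2 to 3 per condition in the other, without saying how many clones or separate cultures these were. If the replicates were not separate cultures, the p-values measure only the spread between these samples.

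Loss of GAS41 was compared with WT to find the genes that depend on it. YEATS4 RNA fell from 623 ± 9.05 normalized reads in WT to 352 ± 32.6 in GAS41-KO (log2 change -0.64, adjusted p = 2.09e-06). YEATS4 RNA was therefore still present in the knockout cells. Interferon response genes rose in the same cells, and genes of ribosome biogenesis and of DNA replication fell, but of these 3 lists only the interferon list remained called with an estimated correlation (adjusted p = 0.000381, against 0.0909 and 0.137). Several epithelial genes were among the largest falls. IFI6, an interferon-induced gene, rose 59.2-fold from 98.8 ± 16.7 to 5850 ± 276. GRHL2, a transcription factor that maintains epithelial identity, fell from 711 ± 4.78 to 6.03 ± 2.69, a level 118-fold lower. In all, 7624 of 14505 tested genes were called, 3772 higher and 3852 lower, and 282 rose and 116 fell by 1 log2 or more.

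The 8 genes with the largest rises on the deposited log2 scale were RGS5, IFI6, IFI27, BMP4, ZBED2, SEMA3A, IFIT1 and TNFSF4. RGS5, a regulator of G protein signalling, went from 90.9 ± 8.69 to 9610 ± 533, a 106-fold rise. The secreted growth factor BMP4 rose 15.7-fold to 13700 ± 242, and the axon guidance ligand SEMA3A rose 17.2-fold to 5920 ± 278. ZBED2 rose 42.4-fold to 2370 ± 69.7. TNFSF4, the ligand OX40L, rose 56-fold to 1210 ± 25.2. The 8 largest falls were MAL2, S100A14, AP1M2, STK39, GRHL2, EPCAM, SLC1A3 and ST14. MAL2, a membrane protein of apical transport, fell from 4780 ± 140 to 151 ± 9.48. AP1M2, the epithelial form of a clathrin adaptor subunit, fell from 1190 ± 41 to 34.8 ± 3.89. The epithelial adhesion molecule EPCAM fell from 7560 ± 351 to 922 ± 17.2, and the epithelial protease ST14 fell from 2720 ± 192 to 294 ± 13.4. S100A14 fell to 95.1 ± 1.54, STK39 to 456 ± 38.7 and the glutamate transporter SLC1A3 to 35.1 ± 7.37.

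**Figure D1:**
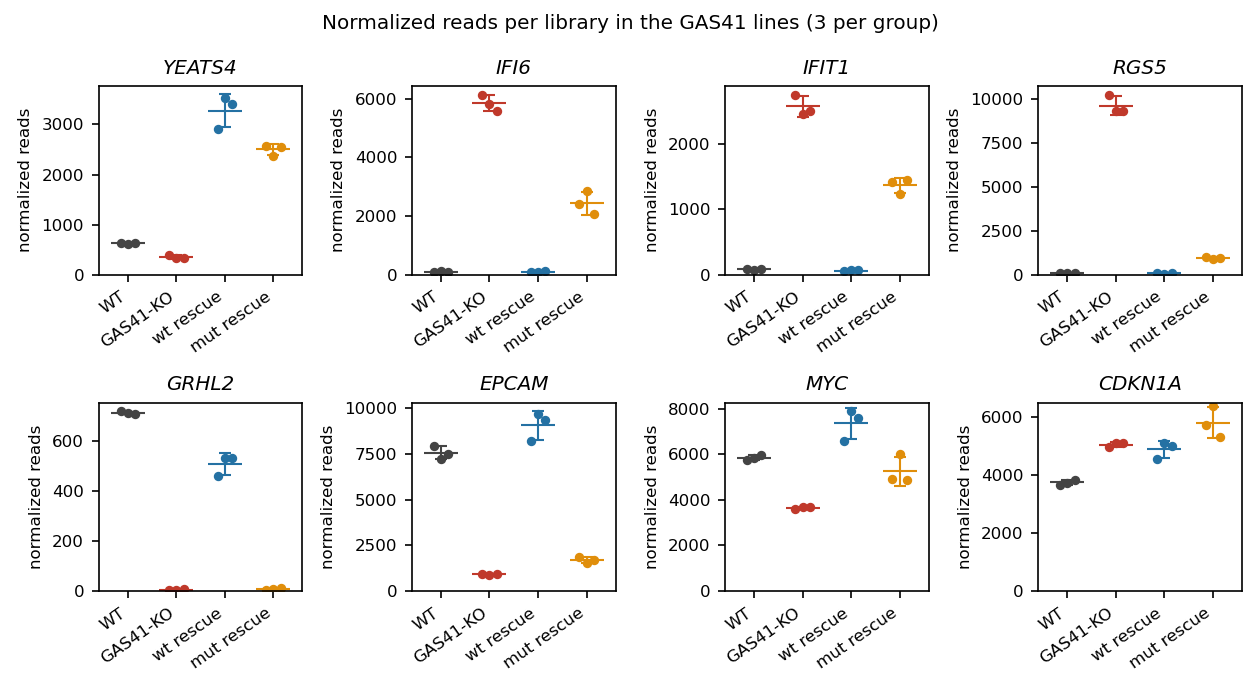
Normalized reads of 8 genes in the 12 libraries of the GAS41 experiment, by group; points are libraries and the bar shows mean ± SD (n = 3). IFI6 stood at 5850 in GAS41-KO, 100 in wt rescue and 2440 in mut rescue.

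All 20 tested genes of the interferon response list rose in GAS41-KO (median log2 change 2.06, camera adjusted p = 5.35e-21, and adjusted p = 0.000381 with an estimated correlation). The count was also 20 when adjusted over the list alone. IFI27 went from 7.34 ± 3.1 to 1940 ± 33.1. IFIT1, which binds foreign RNA, rose 31-fold from 83.3 ± 8.29 to 2580 ± 157. The epithelial-mesenchymal transition list had 7 rises and 3 falls among 10 tested genes (median 0.59, adjusted p = 0.0031, and adjusted p = 0.0726 with an estimated correlation), with the same counts adjusted over the list alone. This list holds mesenchymal genes and transition factors, so its 3 falls run against a transition. CDH1, the E-cadherin of epithelial junctions, is in the colon epithelium list instead, and fell from 1430 ± 17.2 to 139 ± 15.2. The mesenchymal genes VIM, FN1 and SPARC rose. The intermediate filament VIM went from 33.5 ± 7.79 to 343 ± 2.53, and fibronectin FN1 rose 4.82-fold to 1240 ± 35.6.

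Among 33 tested p53 target genes, 20 rose and 1 fell, or 20 and 2 adjusted over the list alone. The median change was 0.23 (adjusted p = 0.000173, and adjusted p = 0.0909 with an estimated correlation). PLK2, a kinase induced by stress, rose 7.92-fold to 4160 ± 76, TP53INP1 rose 3.17-fold to 1380 ± 48.1 and BTG2 rose 2.12-fold to 974 ± 21.1. CDKN1A, which encodes the cell cycle inhibitor p21, rose 1.35-fold from 3750 ± 81.2 to 5060 ± 88.7 (adjusted p = 8.74e-05). MDM2, which encodes a ubiquitin ligase, was at 3330 ± 182 in WT and 3150 ± 49.9 in GAS41-KO (adjusted p = 0.561).

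Of 8 tested histone cluster genes 7 rose, with HIST1H1C up 3.16-fold to 375 ± 36.8 and HIST1H2BD up 4.45-fold to 135 ± 22.3 (median 0.45, adjusted p = 0.00378, and adjusted p = 0.164 with an estimated correlation). Adjusted over the list alone, 7 rose and 1 fell. The list has 20 genes, so most were not tested. Since the GAS41 libraries are of poly-A RNA, histone cluster levels here and below do not cover histone RNA without a poly-A tail. In the NF-kB and inflammatory secretion list 6 of 9 rose and none fell, also adjusted over the list alone (median 0.27, adjusted p = 0.0144, and adjusted p = 0.106 with an estimated correlation). Its inhibitor gene NFKBIA rose from 484 ± 21.5 to 981 ± 27.1. Immediate early genes had 13 rises and 2 falls among 19, also adjusted over the list alone (median 0.29, adjusted p = 0.0159, and adjusted p = 0.491 with an estimated correlation). JUN rose 2.89-fold to 734 ± 15.5, and DUSP6, which switches off ERK, rose 2.33-fold to 6140 ± 103.

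Genes of growth and division fell. In the ribosome biogenesis and MYC-linked list 24 of 25 fell and none rose, also adjusted over the list alone (median -0.48, adjusted p = 7.77e-09, and adjusted p = 0.0909 with an estimated correlation). UTP20, a factor of ribosomal RNA processing, fell from 1630 ± 42.3 to 752 ± 32.7, and MRTO4 fell from 2100 ± 64.1 to 1090 ± 24.3. MYC, the transcription factor that drives such genes, fell from 5860 ± 96.9 to 3660 ± 50.9 (adjusted p = 4.49e-06). In the G1/S and DNA replication list 23 of 26 fell, also adjusted over the list alone (median -0.44, adjusted p = 1.01e-07, and adjusted p = 0.137 with an estimated correlation). The replicative helicase subunit MCM3 fell from 8350 ± 136 to 5250 ± 91.2. In the G2/M and mitosis list 14 of 25 fell, or 15 adjusted over the list alone (median -0.29, adjusted p = 0.000185, and adjusted p = 0.0495 with an estimated correlation). Cyclin A gene CCNA2 fell from 2950 ± 106 to 1720 ± 119.

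Among DNA repair genes 18 of 25 fell, or 20 adjusted over the list alone (median -0.42, adjusted p = 3.2e-06, and adjusted p = 0.178 with an estimated correlation). FANCD2, of the Fanconi crosslink repair pathway, fell from 1980 ± 78.5 to 952 ± 15. Of the cholesterol synthesis genes 14 of 17 fell, also adjusted over the list alone (median -0.51, adjusted p = 5.9e-06, and adjusted p = 0.054 with an estimated correlation). HMGCS1, an early enzyme of that pathway, fell from 2210 ± 54.2 to 973 ± 25.7, and its regulator INSIG1 fell from 1390 ± 42.8 to 567 ± 14.8. The unfolded protein and amino acid stress list had 11 falls and 3 rises among 17, also adjusted over the list alone (median -0.35, adjusted p = 0.0204, and adjusted p = 0.557 with an estimated correlation). TRIB3, a target of the stress factor ATF4, fell from 1240 ± 4.69 to 519 ± 16.6.

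The remaining lists were not called against WT. Histone deacetylase genes moved apart, since HDAC2 fell from 4530 ± 133 to 2580 ± 60.3 (adjusted p = 2.24e-08) and HDAC1 went from 5620 ± 125 to 6580 ± 212 (adjusted p = 0.0134). SIN3A, the scaffold of the SIN3-HDAC corepressor, was at 2350 ± 51.2 in WT and 2240 ± 47.2 in GAS41-KO (adjusted p = 0.419). In the SIN3-HDAC and NCoR list 2 rose and 4 fell among 19. TIP60 and SRCAP subunits had 4 rises and 6 falls among 22, and the helicase RUVBL1 fell from 3590 ± 59.1 to 2390 ± 17.2. The colon epithelium list had 5 rises and 4 falls among 11, with EPCAM and CDH1 among the falls. Wnt targets had 8 rises and 2 falls among 13, with AXIN2 up 5.34-fold to 964 ± 34.4 and RNF43 down from 827 ± 33.7 to 332 ± 17.8. In the hypoxia and glycolysis list 7 rose and 7 fell among 19, with a median of -0.08, a mean of 0.1 and an upward camera direction. SLC2A1, the main glucose transporter, rose 4.07-fold to 4920 ± 128, while the peptide hormone gene ADM fell from 515 ± 3.23 to 142 ± 8.01. Acyl writers, readers and erasers had 5 rises and 2 falls among 20, heat shock genes 1 and 4 among 12, ribosomal protein genes 3 and 1 among 24 and oxidative phosphorylation genes 1 and 6 among 15. The chromosome 12q15 neighbours of YEATS4 had 1 rise and 4 falls among 11, and fibroblast markers 1 and 1 among 3.

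Medians depended on the scale, since the deposited one compresses genes of few reads. In GAS41-KO, voom with the deposited size factors gave 3.06 for interferon genes, 1.53 for histone cluster genes, 1.02 for epithelial-mesenchymal genes, 0.69 for NF-kB genes and 0.44 for immediate early genes.

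Groups did not overlap for 69% of tested genes, where chance gives 10%. For HDAC1, GAS41-KO vs WT, the adjusted p of 0.0134 became 0.0579 without GAS41-KO replicate 1.

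Normal GAS41 was put back to ask which changes return. In wt rescue YEATS4 stood at 3280 ± 326, which was 9.31-fold over GAS41-KO. IFI6 fell back from 5850 ± 276 to 100 ± 21.2, against 98.8 ± 16.7 in WT, and RGS5 fell to 70.9 ± 15.7, against 90.9 ± 8.69. GRHL2 rose from 6.03 ± 2.69 to 506 ± 42.7 and EPCAM from 922 ± 17.2 to 9090 ± 788. MYC rose from 3660 ± 50.9 to 7360 ± 690. Beside YEATS4, the largest rises were those of AP1M2, EPCAM, ST14 and MAL2, and the largest falls those of RGS5, IFI6, IFI27, IFIT1 and TGM2, which fell from 3540 ± 89.4 to 198 ± 22.3. Compared with GAS41-KO, 9571 genes were called, 4783 higher and 4788 lower, and 164 rose and 404 fell by 1 log2 or more.

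All 20 interferon genes fell in wt rescue compared with GAS41-KO (median -2.19, adjusted p = 4.71e-17, and adjusted p = 0.000408 with an estimated correlation). NF-kB genes had 8 falls among 9 (median -0.41, adjusted p = 0.00834, and adjusted p = 0.0909 with an estimated correlation). Histone cluster genes had 7 falls among 8 (median -0.43, adjusted p = 0.00952, and adjusted p = 0.203 with an estimated correlation). The epithelial-mesenchymal list had 6 falls and 1 rise (median -0.4, adjusted p = 0.00232, and adjusted p = 0.0659 with an estimated correlation), and VIM fell to 36.1 ± 3.58. CDH1, of the colon epithelium list, rose to 1360 ± 104. Among p53 targets 16 fell and 4 rose (median -0.19, adjusted p = 0.0183, and adjusted p = 0.241 with an estimated correlation). CDKN1A was at 4890 ± 300, with an adjusted p of 0.541 against GAS41-KO.

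Growth genes rose in the same comparison. Ribosome biogenesis genes had 23 rises among 25 (median 0.85, adjusted p = 1.68e-10, and adjusted p = 0.0726 with an estimated correlation), with MRTO4 at 2970 ± 347. G1/S genes had 25 rises among 26 (median 0.68, adjusted p = 2.61e-09, and adjusted p = 0.106 with an estimated correlation), with MCM3 at 9540 ± 799. G2/M genes had 17 rises and 3 falls (median 0.49, adjusted p = 0.000287, and adjusted p = 0.0523 with an estimated correlation). DNA repair genes had 16 rises and 3 falls (median 0.39, adjusted p = 0.00539, and adjusted p = 0.445 with an estimated correlation). Cholesterol genes had 11 rises and 4 falls (median 0.49, adjusted p = 0.0144, and adjusted p = 0.207 with an estimated correlation). Oxidative phosphorylation genes had 11 rises among 15 (median 0.33, adjusted p = 0.00686, and adjusted p = 0.562 with an estimated correlation). Heat shock genes had 7 rises among 12 (median 0.32, adjusted p = 0.0233, and adjusted p = 0.147 with an estimated correlation). Adjusted over the list alone, 1 G1/S gene fell and 1 histone cluster gene and 12 cholesterol genes rose, and the other counts above were the same.

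On other scales several of these medians differed. Over GAS41-KO, voom with the deposited size factors gave wt rescue medians of -3.35 for interferon genes, -1.44 for histone cluster genes, -0.95 for epithelial-mesenchymal genes and -0.9 for NF-kB genes, and voom with TMM factors -0.29 for p53 targets. With quantile normalization oxidative phosphorylation genes had a median of 0.09 with 6 rises and 1 fall, and heat shock genes 0.18 with 7 rises and 2 falls.

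The 3 wt rescue libraries differed in long transcripts. A list of 40 long transcripts had medians of -0.13, -0.76 and -0.73 log2 from WT in replicates 1, 2 and 3, and ribosomal protein genes had medians of 0.13, 0.32 and 0.35, while mut rescue had 0.17, 0.32 and 0 for the latter. With replicate 1 alone in its group, the spread comes from the other groups, and a single library is assumed to vary like them. In that setting the count for wt rescue vs GAS41-KO was 7430 genes, G2/M genes had 21 rises and DNA repair genes 22 rises and 1 fall. Interferon genes again had 20 falls. Oxidative phosphorylation genes had 7 rises with a median of 0.2, and NF-kB genes 5 falls with a median of -0.38. Ribosomal protein genes had 9 rises among 24 with all libraries, 1 with replicate 1 alone, and 9 falls and 1 rise after quantile normalization.

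Against WT, YEATS4 RNA stood 5.26-fold higher in wt rescue, and 7267 genes were called, of which 14 rose and 79 fell by 1 log2 or more. Ribosome biogenesis genes were above WT, with 20 rises among 25 (median 0.41, adjusted p = 4.01e-06, and adjusted p = 0.147 with an estimated correlation). G1/S genes had 20 rises among 26 (median 0.25, adjusted p = 0.000175, and adjusted p = 0.254 with an estimated correlation), and ribosomal protein genes 21 among 24 (median 0.27, adjusted p = 6.07e-05, and adjusted p = 0.58 with an estimated correlation). TIP60 and SRCAP subunits had 14 rises and 1 fall (median 0.2, adjusted p = 0.00952, and adjusted p = 0.241 with an estimated correlation). Heat shock genes had 7 rises and 1 fall (adjusted p = 0.03, and adjusted p = 0.164 with an estimated correlation). Oxidative phosphorylation genes had 7 rises (adjusted p = 0.0222, and adjusted p = 0.625 with an estimated correlation). Cholesterol genes had 9 falls and 1 rise (median -0.19, adjusted p = 0.0167, and adjusted p = 0.212 with an estimated correlation). The interferon genes IFIH1, IFIT2, IRF9 and IFIT1, named after their values were seen, were below WT and none of the 20 above (median -0.06, adjusted p = 0.193), and the call on IFIT1 was lost without WT replicate 1 or 3 or wt rescue replicate 1. Adjusted over the list alone, ribosomal protein genes had 23 rises, TIP60 and SRCAP subunits 15, ribosome biogenesis genes 1 fall and heat shock genes 2 falls and interferon genes 3 falls, and the counts of G1/S, oxidative phosphorylation and cholesterol genes were the same. With replicate 1 alone, the count for wt rescue vs WT was 2328 genes. The sizes fell as well as the counts: G1/S genes had 6 rises (median 0.15), ribosomal protein genes 0 (median 0.13), TIP60 and SRCAP subunits 3 (median 0.12) and oxidative phosphorylation genes 0 (median 0.06, against 0.16 with all libraries). Ribosome biogenesis genes had 17 rises (median 0.28).

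Most of these rises over WT also depended on the normalization. After quantile normalization ribosomal protein genes had 3 rises and 1 fall over WT (median 0.04), G1/S genes 10 rises (median 0.11), TIP60 and SRCAP subunits 8 rises and 1 fall (median 0.08), heat shock genes 4 rises and 2 falls (median 0.11) and oxidative phosphorylation genes 1 of each (median 0). Ribosome biogenesis genes kept 15 rises against 2 falls (median 0.25), and cholesterol genes had 10 falls (median -0.32).

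Mutant GAS41 was put back to ask what the YEATS domain contributes. YEATS4 in mut rescue stood at 2500 ± 109, which was 7.11-fold over GAS41-KO and 4.01-fold over WT. Interferon genes came down in part: IFI6 fell from 5850 ± 276 to 2440 ± 389 and IFIT1 from 2580 ± 157 to 1370 ± 115. RGS5 fell from 9610 ± 533 to 953 ± 74.4, still above the 90.9 ± 8.69 of WT. GRHL2 was at 7.74 ± 2.14 and CDH1 at 165 ± 13.7, against 711 ± 4.78 and 1430 ± 17.2 in WT. Compared with GAS41-KO, 2164 genes were called, 858 higher and 1306 lower, and 3 rose and 22 fell by 1 log2 or more.

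The largest rises beside that of YEATS4 were those of VGF, LAMB3, CAV1 and PTP4A1. The laminin chain LAMB3 rose 2.49-fold to 802 ± 35.7, and CAV1, the coat protein of caveolae, rose to 3840 ± 257 from 1920 ± 101. VGF was at 263 ± 89 against 65 ± 4.12, and PTP4A1 at 10900 ± 1320 against 5690 ± 251. The largest falls were those of RGS5, TMEM200A, TGM2, HAS2 and FAM84B. HAS2, a hyaluronan synthase, fell from 281 ± 20.6 to 32.6 ± 4.8, and the transglutaminase TGM2 fell from 3540 ± 89.4 to 1050 ± 100. TMEM200A fell from 2320 ± 80.7 to 618 ± 23 and FAM84B from 2060 ± 44.8 to 633 ± 35.8.

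Of 20 interferon genes 19 fell in mut rescue compared with GAS41-KO (median -0.67, adjusted p = 5.11e-27, and adjusted p = 0.000292 with an estimated correlation). NF-kB genes had 6 falls among 9, or 8 adjusted over the list alone (median -0.25, adjusted p = 1.4e-05, and adjusted p = 0.0265 with an estimated correlation). Ribosome biogenesis genes had 19 rises among 25, or 23 adjusted over the list alone (median 0.27, adjusted p = 4.65e-14, and adjusted p = 0.0495 with an estimated correlation). MYC rose from 3660 ± 50.9 to 5260 ± 640. Wnt targets had 9 falls and 2 rises among 13 (median -0.28, adjusted p = 0.000311, and adjusted p = 0.203 with an estimated correlation). Epithelial-mesenchymal genes had 5 falls (median -0.19, adjusted p = 0.00117, and adjusted p = 0.054 with an estimated correlation), with FN1 down to 600 ± 11.1. Of the G2/M and G1/S genes 0 were called in either direction. Adjusted over the list alone, interferon genes had 20 falls, Wnt targets 11, and epithelial-mesenchymal genes 6 falls and 1 rise.

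Smaller shifts in mut rescue were called for 4 further lists, each lost with an estimated correlation. Histone cluster genes had 3 rises (median 0.14, adjusted p = 0.00253, and adjusted p = 0.147 with an estimated correlation). The p53 targets had 7 rises (median 0.07, adjusted p = 0.0117, and adjusted p = 0.21 with an estimated correlation). Heat shock genes had 3 rises (median 0.1, adjusted p = 0.0123, and adjusted p = 0.115 with an estimated correlation). TIP60 and SRCAP subunits had 4 rises (median 0.07, adjusted p = 0.022, and adjusted p = 0.317 with an estimated correlation). With counts adjusted over the list alone, p53 targets had 11 rises and 2 falls and heat shock genes 4 rises. In voom with the deposited size factors, medians of mut rescue over GAS41-KO were 0.42 for histone cluster genes, -0.86 for interferon genes, -0.46 for Wnt targets, -0.41 for NF-kB genes and -0.3 for epithelial-mesenchymal genes.

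Against WT, mut rescue had 6718 called genes, and interferon genes had 19 rises among 20 (median 1.43, adjusted p = 2.76e-19, and adjusted p = 0.000381 with an estimated correlation). The p53 targets had 24 rises and 1 fall among 33 (median 0.45, adjusted p = 1.81e-08, and adjusted p = 0.0383 with an estimated correlation), with CDKN1A at 5810 ± 532. Cholesterol genes had 15 falls among 17 (median -0.57, adjusted p = 4.54e-08, and adjusted p = 0.0383 with an estimated correlation), and G2/M genes 15 among 25 (median -0.28, adjusted p = 7.58e-05, and adjusted p = 0.0428 with an estimated correlation). G1/S genes had 21 falls among 26 (median -0.35, adjusted p = 1.85e-07, and adjusted p = 0.143 with an estimated correlation). DNA repair genes had 16 falls among 25 (median -0.35, adjusted p = 5e-06, and adjusted p = 0.187 with an estimated correlation). Histone cluster genes had 7 rises and 1 fall (median 0.69, adjusted p = 0.000167, and adjusted p = 0.0909 with an estimated correlation). Ribosome biogenesis genes had 12 falls and 1 rise (median -0.17, adjusted p = 0.00625, and adjusted p = 0.393 with an estimated correlation). Epithelial-mesenchymal genes had 6 rises and 2 falls (adjusted p = 0.00891, and adjusted p = 0.0909 with an estimated correlation). Immediate early genes had 11 rises and 4 falls (adjusted p = 0.0146, and adjusted p = 0.485 with an estimated correlation). Ribosomal protein genes had 8 rises, or 0 adjusted over the list alone (adjusted p = 0.0203, and adjusted p = 0.754 with an estimated correlation). The unfolded protein and amino acid stress list had 8 falls and 2 rises (adjusted p = 0.0318, and adjusted p = 0.58 with an estimated correlation). Adjusted over the list alone, interferon genes had 20 rises, p53 targets 25 and immediate early genes 13, while G1/S genes had 23 falls, DNA repair genes 17, G2/M genes 16 and ribosome biogenesis genes 13. Over WT, voom with the deposited size factors gave mut rescue medians of 2.43 for interferon genes, 1.97 for histone cluster genes, 0.78 for epithelial-mesenchymal genes and 0.45 for immediate early genes, and ribosomal protein genes had 0.09 with quantile normalization.

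Groups did not overlap for 33.7% of genes between mut rescue and GAS41-KO, where chance gives 10%. For mut rescue vs GAS41-KO the count of 2164 called genes became 1418, 1375 and 1283 without GAS41-KO replicates 1, 2 and 3, and 1419 without mut rescue replicate 1.

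The direct comparison of both rescue lines asks what an intact YEATS domain adds. YEATS4 was at 2500 ± 109 in mut rescue and 3280 ± 326 in wt rescue. IFI27 was 77.6-fold higher in mut rescue, at 665 ± 110 against 8.57 ± 2.4, and the chemokine receptor CXCR4 was 77.1-fold higher, at 634 ± 49.1 against 8.23 ± 1.91. IFI6 was 24.4-fold and IFIT1 22.8-fold higher. NEBL was at 4140 ± 371 against 280 ± 43. The largest falls in mut rescue were those of ADGRF1, MAL2, ALDH1A3, AP1M2 and GRHL2. ALDH1A3, a retinoic acid synthesis enzyme, was at 1350 ± 42.1 against 11200 ± 820, and ADGRF1 at 189 ± 17.7 against 2670 ± 133.

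Between the rescue lines 8860 genes were called, 4322 higher and 4538 lower in mut rescue. All 20 interferon genes were higher (median 1.46, adjusted p = 1.1e-16, and adjusted p = 0.000408 with an estimated correlation). G1/S genes had 25 of 26 lower (median -0.59, adjusted p = 4.77e-10, and adjusted p = 0.0909 with an estimated correlation). Ribosome biogenesis genes had 23 of 25 lower (median -0.55, adjusted p = 1.01e-07, and adjusted p = 0.106 with an estimated correlation). G2/M genes had 17 lower and 3 higher (median -0.51, adjusted p = 8.48e-05, and adjusted p = 0.0428 with an estimated correlation). The p53 targets had 23 higher and 2 lower (median 0.25, adjusted p = 5.84e-05, and adjusted p = 0.0869 with an estimated correlation). Histone cluster genes had 7 higher and 1 lower (median 0.7, adjusted p = 0.000471, and adjusted p = 0.108 with an estimated correlation). Cholesterol genes had 11 lower and 2 higher (median -0.4, adjusted p = 0.00244, and adjusted p = 0.137 with an estimated correlation). DNA repair genes had 16 lower and 4 higher (median -0.36, adjusted p = 0.00897, and adjusted p = 0.478 with an estimated correlation). Epithelial-mesenchymal genes had 5 higher and 2 lower (median 0.37, adjusted p = 0.00897, and adjusted p = 0.0909 with an estimated correlation). Oxidative phosphorylation genes had 10 lower (median -0.25, adjusted p = 0.00972, and adjusted p = 0.58 with an estimated correlation). When adjusted over the list alone, 1 G1/S gene and 5 DNA repair genes were higher, and the other counts were the same. Oxidative phosphorylation genes had 5 lower (median -0.08) with quantile normalization, and p53 targets a median of 0.39 in voom with TMM factors. The long-transcript list had 29 higher and 4 lower among 40, beside the low values of wt rescue replicates 2 and 3. With wt rescue replicate 1 alone, the count for mut rescue vs wt rescue was 6127 genes, and interferon genes had 19 higher, G1/S genes 24 lower, ribosome biogenesis genes 21 lower and oxidative phosphorylation genes 6 lower (median -0.14).

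**Figure D2:**
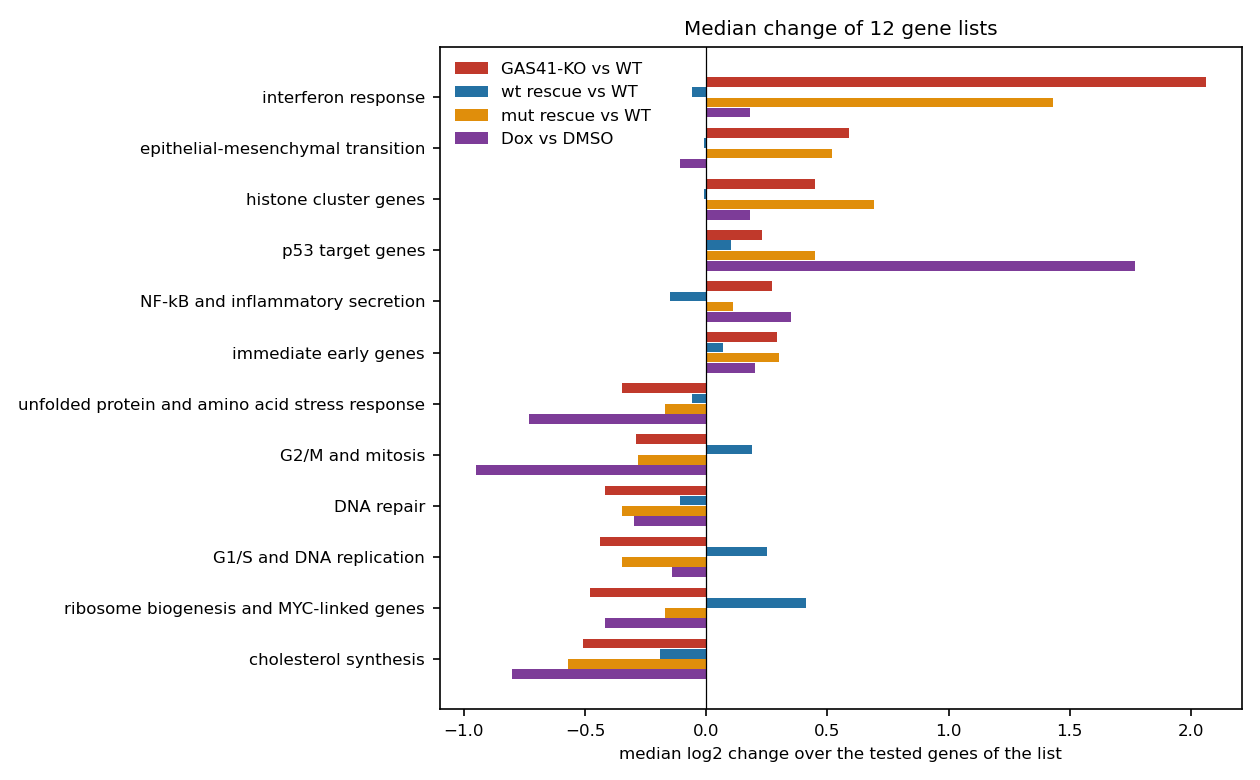
Median log2 change of 12 gene lists (horizontal bars) for GAS41-KO, wt rescue and mut rescue over WT and for doxorubicin over DMSO. Interferon genes stood at 2.06 in GAS41-KO, -0.06 in wt rescue and 1.43 in mut rescue.

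Return of the knockout changes was counted over the 3772 genes that rose and the 3852 that fell in GAS41-KO. In wt rescue 5842 of these genes were called in the opposite direction over GAS41-KO, and 183 in the same direction. In mut rescue 1469 were called in the opposite direction and 244 in the same direction. Return in mut rescue counted 918 genes without GAS41-KO replicate 2, 875 without GAS41-KO replicate 3 and 968 without mut rescue replicate 1. Of the genes up in GAS41-KO, 2502 were higher and 119 lower in mut rescue than in wt rescue. Of the genes down in GAS41-KO, 2826 were lower and 103 higher. Both contrasts share the GAS41-KO libraries, which alone pushes them apart: across genes, their Pearson r was -0.804 for wt rescue and -0.49 for mut rescue, and -0.0925 in simulated rescue libraries that did not change. Independent lists of the same sizes would give 2515 opposite calls for wt rescue and 567 for mut rescue. Genes are not independent replicates, and the 3 GAS41-KO libraries are too few to be split between the contrasts.

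**Figure D3:**
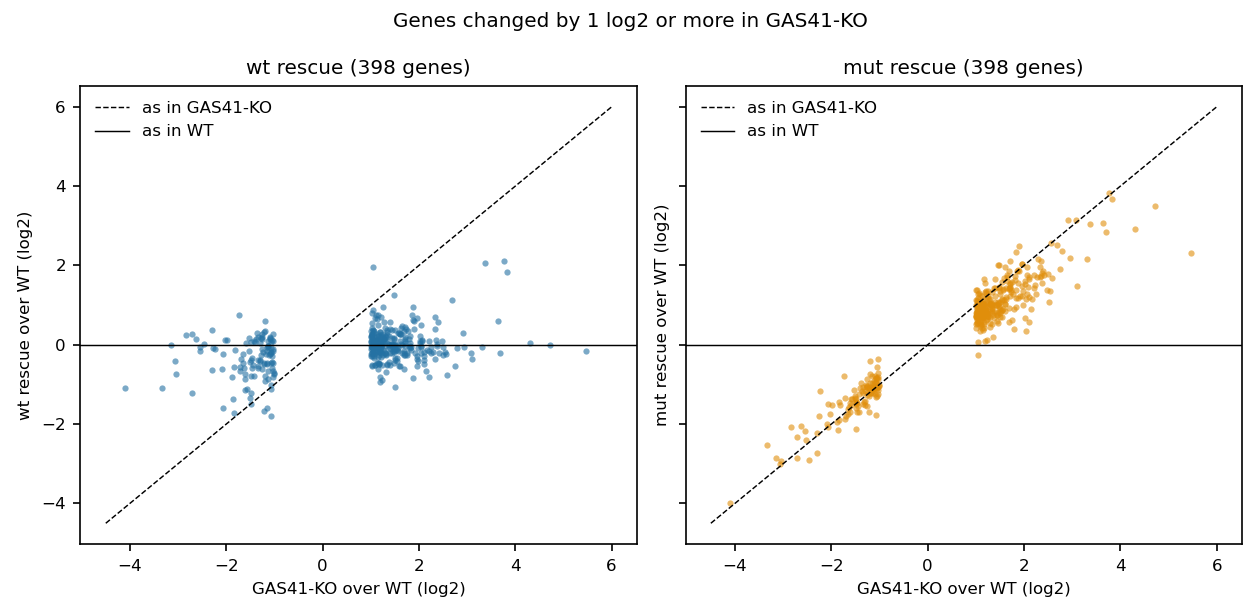
Log2 change in GAS41-KO over WT (x axis) and in wt or mut rescue over WT (y axis) for the 398 genes that changed by 1 log2 or more in GAS41-KO; the solid line marks the WT level and the dashed line the GAS41-KO level. The 282 raised genes had medians of -0.03 in wt rescue and 1.03 in mut rescue.

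Of the 282 genes up by 1 log2 or more in GAS41-KO, 280 were called in the opposite direction in wt rescue and 187 in mut rescue, and of the 116 down by as much, 107 and 34. The 282 raised genes had a median of 1.36 in GAS41-KO, -0.03 in wt rescue and 1.03 in mut rescue, each over WT. The 116 lowered genes had medians of -1.33, -0.31 and -1.27. BMP4 returned in part in wt rescue, to 4320 ± 400, and not in mut rescue, at 14500 ± 1150. ZBED2 was at 491 ± 57.2 in wt rescue and 2130 ± 44.5 in mut rescue. MAL2 was at 2180 ± 45.3 and 174 ± 26.4, AP1M2 at 1180 ± 151 and 61.2 ± 5.63, and EPCAM at 9090 ± 788 and 1680 ± 163.

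**Figure D4:**
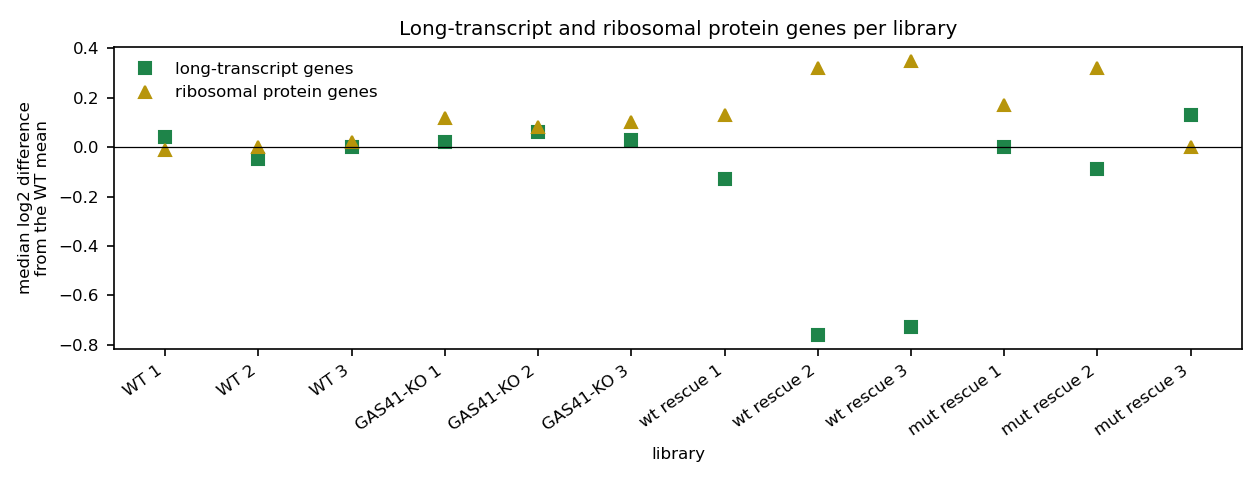
Median log2 change from the WT mean of 40 long transcripts and of the cytosolic ribosomal protein genes in each of the 12 libraries, by group. Replicates 2 and 3 of wt rescue stand at -0.76 and -0.73 for long transcripts, and replicate 1 at -0.13.

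Doxorubicin was compared with DMSO to describe the response of these cells to DNA damage. YEATS4 fell from 671 ± 48.6 to 186 ± 10.8 (log2 change -1.25, adjusted p = 3.58e-09). Targets of p53 rose together: CDKN1A rose 10.8-fold from 5630 ± 369 to 61000 ± 1610, MDM2 rose 5.34-fold to 11400 ± 439 and TP53I3, a quinone oxidoreductase, rose 53.1-fold to 16500 ± 1340. The mitotic kinase gene PLK1 fell from 3560 ± 357 to 681 ± 43.6. Of 14195 tested genes 9326 were called, 4591 higher and 4735 lower, and 692 rose and 209 fell by 1 log2 or more.

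The 8 largest rises on the deposited log2 scale were those of TP53I3, SORCS2, H19, ABCA12, SULF2, AQP3, LAMP3 and CDKN1A. SORCS2, a sorting receptor, went from 10.3 ± 3.17 to 4020 ± 172, a 389-fold rise. The imprinted noncoding RNA H19 rose 125-fold to 2570 ± 18.1. ABCA12, a lipid transporter, rose 37.3-fold to 2350 ± 257, and LAMP3 rose 26.9-fold to 2710 ± 221. SULF2 was at 5170 ± 116 against 286 ± 20.9 and the water channel AQP3 at 4340 ± 195 against 231 ± 17.9. The 8 largest falls were those of RPL22L1, SCD, MALL, PLK1, ASNS, BUB1, HNRNPD and DEPDC1. RPL22L1, a paralog of a ribosomal protein, fell from 5010 ± 889 to 541 ± 66. SCD, the fatty acid desaturase, fell from 42400 ± 1280 to 7000 ± 332, and the asparagine synthetase ASNS fell from 5930 ± 486 to 1310 ± 61.8. BUB1, of the spindle checkpoint, fell to 671 ± 17.4, MALL to 745 ± 19.5, HNRNPD to 1970 ± 149 and DEPDC1 to 437 ± 60.3.

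**Figure D5:**
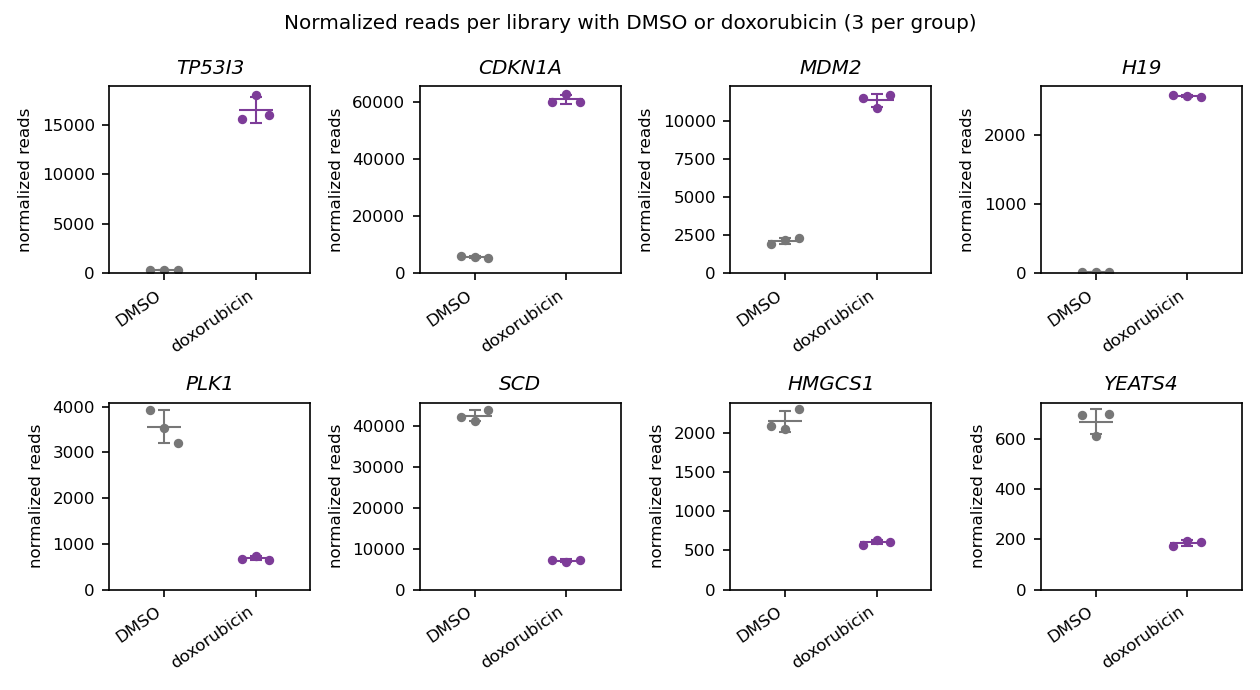
Normalized reads of 8 genes in the 6 libraries of the doxorubicin experiment, DMSO against doxorubicin; points are libraries and the bar shows mean ± SD (n = 3). CDKN1A stood at 5630 with DMSO and 61000 with doxorubicin, and YEATS4 at 671 and 186.

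All 33 tested p53 targets rose, also adjusted over the list alone (median 1.77, adjusted p = 1.64e-19, and adjusted p = 0.0265 with an estimated correlation). BTG2 rose 9.77-fold to 5820 ± 74. G2/M genes had 23 falls among 25, or 24 adjusted over the list alone (median -0.95, adjusted p = 1.68e-10, and adjusted p = 0.0726 with an estimated correlation). CDC20, the activator of anaphase, fell from 6980 ± 341 to 1970 ± 135. Cholesterol genes had 15 falls among 17, or 16 adjusted over the list alone (median -0.8, adjusted p = 3.98e-07, and adjusted p = 0.137 with an estimated correlation). HMGCS1 fell from 2150 ± 136 to 607 ± 30 and INSIG1 from 2000 ± 46.2 to 406 ± 5.06. The unfolded protein and amino acid stress list had 13 falls and 2 rises among 17, also adjusted over the list alone (median -0.73, adjusted p = 0.000185, and adjusted p = 0.357 with an estimated correlation). CHAC1, a stress-induced glutathione-degrading enzyme, fell from 720 ± 96.1 to 112 ± 6.23.

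Ribosomal protein genes had 18 falls and 1 rise among 24, or 19 and 1 adjusted over the list alone (median -0.41, adjusted p = 0.000287, and adjusted p = 0.649 with an estimated correlation), with RPL3 down from 58300 ± 2510 to 20600 ± 1910. Ribosome biogenesis genes had 16 falls and 3 rises among 25, also adjusted over the list alone (median -0.42, adjusted p = 0.003, and adjusted p = 0.387 with an estimated correlation), with the nucleolar protein gene NPM1 down from 52900 ± 5560 to 25100 ± 835. TIP60 and SRCAP subunits had 16 falls and 1 rise among 22, or 17 and 1 adjusted over the list alone (median -0.34, adjusted p = 0.00123, and adjusted p = 0.241 with an estimated correlation). ACTL6A, an actin-like subunit, fell from 1740 ± 136 to 840 ± 25, and H2AFZ, the gene of histone H2A.Z that these complexes handle, fell from 18300 ± 3030 to 7720 ± 590. DNA repair genes had 15 falls and 3 rises among 25, also adjusted over the list alone (median -0.3, adjusted p = 0.0283, and adjusted p = 0.569 with an estimated correlation). Mismatch repair gene MSH6 fell from 2230 ± 204 to 1110 ± 62.3, while RAD51C rose from 1610 ± 70.1 to 4200 ± 265.

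Beside p53 targets, called lists with more rises than falls were NF-kB, colon epithelium and interferon genes. NF-kB genes had 8 rises among 11 (median 0.35, adjusted p = 0.00269, and adjusted p = 0.173 with an estimated correlation). The adhesion molecule ICAM1 went from 2.97 ± 1.65 to 263 ± 18.9 normalized reads. Colon epithelium genes had 9 rises and 1 fall among 12 (median 0.53, adjusted p = 0.00962, and adjusted p = 0.212 with an estimated correlation). The mucin MUC2 went from 2.31 ± 1.12 to 178 ± 6.03 and the keratin KRT20 from 16.3 ± 3.56 to 100 ± 10.6. Interferon genes had 9 rises and 1 fall among 16 (median 0.18, adjusted p = 0.0146, and adjusted p = 0.203 with an estimated correlation). ISG15, a ubiquitin-like modifier, rose 5.34-fold to 8390 ± 994. Counts adjusted over the list alone were the same for these 3 lists. Their sizes depended on the scale: interferon genes had a median of 0.6 in voom with the deposited size factors and 0.11, with 7 rises and 1 fall, after quantile normalization, and NF-kB genes 0.66 in voom. Ribosomal protein genes had -0.18, with 15 falls and 3 rises, after quantile normalization.

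Other lists were not called with doxorubicin. G1/S genes had 5 rises and 12 falls among 26: PCNA, the replication clamp, rose from 4950 ± 178 to 11900 ± 648, and MCM6 fell from 6080 ± 82 to 2460 ± 32.5. SIN3-HDAC and NCoR genes had 5 rises and 9 falls among 19. SIN3A fell from 1920 ± 60.8 to 1090 ± 88.7 and HDAC2 from 4650 ± 143 to 2970 ± 99.9. HDAC1 fell from 6980 ± 69.9 to 5950 ± 244 (adjusted p = 0.0113). MYC was at 6860 ± 379 with DMSO and 6070 ± 72.6 with doxorubicin (adjusted p = 0.0499). Epithelial-mesenchymal genes had 4 rises and 5 falls among 11, with a median of -0.11, a mean of 0.16 and a downward camera direction. Acyl writers, readers and erasers had 6 rises and 9 falls among 20, with a median of -0.14, a mean of 0.01 and a downward direction; KAT2B rose from 129 ± 10.4 to 548 ± 54.6. The chromosome 12q15 neighbours of YEATS4 had 3 rises and 3 falls among 11, with a median of 0.02, a mean of 0.09 and a downward direction, and their median turned to -0.07 with quantile normalization. Immediate early genes had 10 rises and 6 falls among 19, hypoxia genes 9 and 6 among 19, Wnt targets 5 and 4 among 13 and histone cluster genes 4 and 1 among 7. Heat shock genes had 3 rises and 7 falls among 12, oxidative phosphorylation genes 2 and 8 among 15 and fibroblast markers 2 and 0 among 4.

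Groups did not overlap for 69.1% of tested genes, where chance gives 10%. The labels do not state the treatment time. For HDAC1, Dox vs DMSO, the adjusted p of 0.0113 became 0.0719 without doxorubicin replicate 1 and 0.0587 without replicate 3; for MYC, Dox vs DMSO, it rose from 0.0499 to between 0.0583 and 0.153 without DMSO replicate 1 or 2 or any doxorubicin library.

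Overlap of the knockout and the doxorubicin response was tested over the genes measured in both experiments. YEATS4 fell in both. Of these 13803 genes, 1754 were higher in both, where independent lists would share 1107 (Fisher's exact test, odds ratio 2.95, adjusted p = 5.86e-155). There were 1980 genes lower in both, where independent lists would share 1308 (odds ratio 2.83, adjusted p = 1.75e-154). Opposite changes were fewer than for independent lists: 748 genes were higher in GAS41-KO and lower with doxorubicin (odds ratio 0.413, adjusted p = 1.85e-90), and 770 the reverse (odds ratio 0.47, adjusted p = 2.5e-66). Across genes, which are not independent replicates, the Pearson r of the changes was 0.24 and the Spearman rho 0.31. Among changes of 1 log2 or more, 44 genes were higher in both, where independent lists would share 12.4 (odds ratio 4.27), and 12 were lower in both, against 1.76 (odds ratio 7.9). Large opposite changes were not fewer than for independent lists: 7 genes were higher in GAS41-KO and lower with doxorubicin, against 3.94 (odds ratio 1.83, adjusted p = 0.119), and 15 the reverse, against 5.55 (odds ratio 3, adjusted p = 0.000471).

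Some of the shared genes are members of the fixed lists. No number expected for independent lists was computed for single lists. Of the p53 targets 20 of 33 were higher in both, among them CDKN1A, BTG2 and PLK2, whose log2 changes were 2.68 in GAS41-KO and 2.69 with doxorubicin. All 33 rose with doxorubicin, so this count is simply that of the rises in GAS41-KO. Interferon genes had 9 of 16 higher in both, with ISG15 up by 2.07 and 2.28 and IFI6 by 4.71 and 1.14, and 1 was higher in GAS41-KO and lower with doxorubicin. Cholesterol genes had 13 of 17 lower in both, ribosome biogenesis genes 15 of 25, G2/M genes 12 of 25, G1/S genes 12 of 26, DNA repair genes 11 of 25 and stress response genes 9 of 17. The reverse, lower in GAS41-KO and higher with doxorubicin, held for 4 G1/S genes, 3 ribosome biogenesis genes, 3 DNA repair genes, 2 stress response genes, 1 p53 target and no cholesterol or G2/M gene. Of the stress response genes 1 was higher in GAS41-KO and lower with doxorubicin. HMGCS1, INSIG1, SCD and TRIB3 were lower in both by 1 log2 or more. Of the epithelial-mesenchymal genes 4 of 10 were higher in GAS41-KO and lower with doxorubicin, and 3 were higher in both. Of the colon epithelium genes 4 of 11 were higher in both, 1 was lower in both and 2 were lower in GAS41-KO and higher with doxorubicin.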

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

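Of the tests below, only the counts over other splits of the libraries were chosen before the results were seen; the tests of the interferon genes and of the return of knockout changes were chosen after. The rescue lines differed by a test of the difference itself in 8860 genes, since their changes are both taken over the same GAS41-KO libraries. Of 84 named genes 76 differed, against 61.1% of all tested genes. The named genes include the largest called changes of this comparison and of GAS41-KO over WT, so their share was raised by the choice. Among 23 lists 10 differed, with medians of mut over wt rescue of 1.46 for interferon genes, 0.7 for histone cluster genes, 0.37 for epithelial-mesenchymal genes and 0.25 for p53 targets. Lower medians were -0.59 for G1/S genes, -0.55 for ribosome biogenesis genes, -0.51 for G2/M genes, -0.4 for cholesterol genes, -0.36 for DNA repair genes and -0.25 for oxidative phosphorylation genes. On the deposited scale these sizes are compressed for genes of few reads: voom with the deposited size factors, chosen after the data were seen, gave 2.74 for interferon genes, 1.89 for histone cluster genes and 1.01 for epithelial-mesenchymal genes. With an estimated correlation, the difference held for interferon genes and G2/M genes.

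Each comparison of 3 libraries with 3 allows 10 splits, too few for a share under 0.05, and in each the real split was the 1 with the most calls. The real split called 9326 genes for doxorubicin, 7624 for GAS41-KO over WT, 9571 for wt rescue over GAS41-KO, 2164 for mut rescue over GAS41-KO, 7267 for wt rescue over WT and 6718 for mut rescue over WT, and the highest other split of each called 0. Between the rescue lines the real split called 8860 and the highest other 605.

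All 20 interferon genes rose in GAS41-KO with a median of 2.06 log2, and the explanations weighed were reads from blood or immune cells and a difference of the knockout line that GAS41 does not set. Reads from blood or immune cells are argued against by 11 markers with a median of 2 normalized reads in GAS41-KO, where LYZ at 46.2, ITGAX at 39.8 and HBA2 at 10.4 were the most abundant, and LYZ and ITGAX also had 19.8 and 21.7 in WT. A difference that GAS41 does not set is argued against by the median of -0.06 over WT in wt rescue, where all 20 genes had come down, if that line was made from knockout cells as the labels say. Mutant GAS41 lowered the same genes to a median of 1.43 over WT. Whether GAS41 acts on these genes directly was not tested, and how many clones each line stands for remains open.

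Of 7624 knockout changes 5842 were called in the opposite direction in wt rescue and 1469 in mut rescue (for return in mut rescue, 918 without GAS41-KO replicate 2, 875 without GAS41-KO replicate 3 and 968 without mut rescue replicate 1), with 187 of the 282 large rises among the latter, and the explanations weighed were the shared GAS41-KO libraries alone, a wt rescue line made from WT cells and too little mutant GAS41 RNA. The shared libraries alone gave 0.25 opposite calls on average and at most 1 in 20 simulations, against 5842 in wt rescue, though part of that count may still come from sharing. The simulated lines did not differ from GAS41-KO, so few calls were bound to result. A line with real but unrelated changes was not simulated, and independent lists would give 2515 opposite calls for wt rescue. A wt rescue line made from the WT cells is argued against by genes with at least 30 normalized reads in every WT library that were lost elsewhere (every library under 20 percent of the WT mean): 73 were lost in GAS41-KO and 15 in wt rescue, and 8 in both, where independent lists would share 0.0911 (Fisher's exact test, p = 7.78e-15), and ZC4H2, named after its values were seen, had 91.9 ± 13.1 normalized reads in WT and 0 in every library of both lines. Of the 398 large changes 39 were called in wt rescue over WT and lay nearer to GAS41-KO than to WT, and 8 lay as far on the other side. The two-sided exact binomial p was 5.54e-06, with 25 against 1 among lowered genes (p = 8.05e-07) and 14 against 7 among raised genes (p = 0.189). These binomial p-values cannot decide the origin, because both contrasts share the WT libraries. The lists of lost genes share them too, and Fisher's test takes every gene as equally likely to be lost. Its p-value therefore cannot decide the origin by itself. In addition, wt rescue over WT had 79 falls and 14 rises of 1 log2 or more, which puts lowered genes on the knockout side whatever the origin. A WT subclone with the same losses, or the same losses from added GAS41, was not tested. Too little mutant RNA is argued against by YEATS4 at 4.01-fold over WT in mut rescue. These reads do not separate mutant RNA from the YEATS4 RNA left in the knockout cells, which stood at 352 ± 32.6 in GAS41-KO. YEATS4 was also lower in mut rescue than in wt rescue, at 2500 ± 109 against 3280 ± 326. The amount and folding of the mutant protein and differences between clones were not measured and stay open, so a need for the YEATS domain is a hypothesis.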

How the results depend on the processing

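The voom, TMM and quantile settings and wt rescue replicate 1 alone were chosen after seeing the data; the others were planned. Named genes kept their direction and side of the threshold in 6530 checks, became stronger in 53, weaker in 175 and reversed in 5. Lists did so in 377 checks, with 44 stronger, 61 weaker and 1 reversed, and counts and medians in 170, with 29 moved. Where values moved or reversed, the cause was not tested, except that a stricter minimum change leaves fewer calls.

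For wt rescue vs WT the count was 2328 with wt rescue replicate 1 alone. For median mut over wt rescue, genes up in KO, the value was 0.268 on the deposited scale, 0.436 in voom with the deposited size factors, 0.482 with TMM factors, 0.245 with quantile normalization and 0.285 with replicate 1 alone, and 0.251 to 0.288 leaving out single libraries. For median mut over wt rescue, genes down in KO, the values in that order were -0.343, -0.473, -0.406, -0.31 and -0.31, and -0.378 to -0.332 leaving out single libraries. With calls of 1 log2 or more, the overlaps of GAS41-KO and doxorubicin were 44, 12, 7 and 15 genes. Quantile normalization reversed HDAC1, mut rescue vs wt rescue, at 0.139, RPL13, mut rescue vs wt rescue, at 0.162, H2AFZ, wt rescue vs WT, at -0.066, HSPD1, wt rescue vs WT, at -0.213 and MCM3, wt rescue vs WT, at -0.002. For epithelial-mesenchymal transition, Dox vs DMSO, fry gave the upward direction, with a signed -log10 adjusted p of 4.53.

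Leaving out 1 library at a time, the count for mut rescue vs GAS41-KO ran from 1283 (without GAS41-KO replicate 3) to 2374, and return in mut rescue from 875 to 1588. The counts ran from 8414 to 9526 for Dox vs DMSO, 6652 to 6866 for GAS41-KO vs WT, 8620 to 10138 for wt rescue vs GAS41-KO, 7713 to 9518 for mut rescue vs wt rescue, 5585 to 8428 for wt rescue vs WT and 5692 to 6610 for mut rescue vs WT. The replicate block gave 9238 genes for Dox vs DMSO, 7890 for GAS41-KO vs WT and 2403 for mut rescue vs GAS41-KO, and replicate numbers did not pair libraries across groups. A fit on the 2 groups alone gave 9736 genes for GAS41-KO vs WT, against 7624 in the shared fit. For mut rescue vs wt rescue it gave 7415, against 8860. It gave 9285 for wt rescue vs GAS41-KO, 2240 for mut rescue vs GAS41-KO, 6750 for wt rescue vs WT and 6973 for mut rescue vs WT. The counts therefore depend on which groups share 1 estimate of the spread. edgeR with RLE factors and DESeq2 were planned and not run, although the recovered reads would have allowed them, and voom on those reads is the nearest test that was made.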

Other observations

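Genes in this paragraph and the next were chosen after their values were seen, and so was each test in this part. In GAS41-KO 16 genes with under 10 reads in every WT library reached a mean of 100 normalized reads or more. The 2'-5' oligoadenylate synthetase OAS1 went from 2.56 ± 2.01 in WT to 781 ± 21.9, and stood at 2.1 ± 2.1 in wt rescue and 279 ± 26.5 in mut rescue. CXCR4 went from 1.91 ± 2.53 to 517 ± 19.9, and the growth factor TGFB2 from 5.43 ± 3.1 to 239 ± 21.4, with 231 ± 31 in mut rescue. Others of these genes were ANKRD1, ELMO1, HAS2, SNAP25, STC1 and TCF21. The reverse held for 3 genes, ALDH1L1, CCDC64B and GRHL2, and ALDH1L1 went from 122 ± 8.55 to 1.01 ± 1.74 and 12.4 ± 3.69 in wt rescue.

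In GAS41-KO, STAT2, which carries the interferon signal to the nucleus, rose from 577 ± 25.5 to 1640 ± 19.4, and B2M, the shared chain of class I HLA molecules, from 4480 ± 195 to 11500 ± 554. IRF1 rose from 322 ± 18.6 to 610 ± 23.6, and stood at 408 ± 38.3 in wt rescue and 513 ± 43.1 in mut rescue. Epithelial splicing factor ESRP1 fell from 3710 ± 86 to 518 ± 26.3 and stood at 712 ± 11.2 in mut rescue. ZEB1, a repressor of epithelial genes, rose from 82.9 ± 10.2 to 751 ± 19.9. Other epithelial genes did not fall: keratin KRT8 rose from 27200 ± 1340 to 37000 ± 191, KRT18 from 12900 ± 479 to 16800 ± 648 and the claudin CLDN3 from 87.7 ± 9.89 to 124 ± 13.6, while the intestinal factor CDX2 was at 237 ± 22.2 and 217 ± 19.9 (adjusted p = 0.426). CLDN4 fell from 1860 ± 54.6 to 1410 ± 43. ZC4H2 had 91.9 ± 13.1 normalized reads in WT and 0 reads in every GAS41-KO, wt rescue and mut rescue library. NEUROD1 stood at 1.92 normalized reads in WT, 64.6 in GAS41-KO, 216 in wt rescue and 3.7 in mut rescue.

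Long transcripts were lower in the wt rescue libraries, and the explanations weighed were a loss of long transcripts in single libraries and an effect of GAS41 shared by the wt rescue libraries. The median of 40 long transcripts, set against WT, had a range of 0.64 over the wt rescue replicates, where the other groups had at most 0.22 and 10000 random lists at most 0.25. A shared effect of GAS41 stays open: the smallest fall was 16.6 percent of the largest, but this rests on 1 library, replicate 1. Replicate 1 also had the lowest YEATS4 level of the 3 (2911 against 3528 and 3400 normalized reads). Its ribosomal protein median was the lowest as well, at 0.13 log2 from WT against 0.32 and 0.35. The lower YEATS4 level may therefore be part of a wider difference between the libraries, and does not show less GAS41 in replicate 1. A loss in 2 of the 3 libraries, such as by RNA breakage or a difference in library making, also fits the range, and the labels do not name a source.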
